A study of Mus musculus with 98 samples.

How the data were processed

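Gene expression was measured on 98 Agilent 2-colour mouse arrays that compared lung RNA with a common pool of mouse reference RNA. Per the labels, tumors or normal lungs were snap frozen, total RNA was taken up with a column kit, and 10 µg was labelled directly with Cy3 or Cy5. Each of 49 RNA extracts was hybridised on 2 arrays with the dyes exchanged. The extracts were 18 tumors of a HER2 model, 18 tumors of a KRAS model and 13 normal lungs. Of the normal lungs, 3 were C57Bl6, 3 were 129SvEv, 4 came from HER2 chimeras in which the transgene was not induced, and 3 had no strain in the labels. The labels do not say which tumors came from the same animal, so p-values measure the spread between these extracts, which may share animals.

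The deposited scanner files were written by Agilent Feature Extraction 7.5.1, per the submitters' processing notes. Per the file headers they hold, for each spot, the mean signal and the local background median of each channel as intensity values on a linear scale, with no normalization. The same deposited files hold a log10 ratio of red over green for each spot, for which the authors' software had subtracted a background, normalized the dyes and replaced dim signals by surrogate values. They also hold other values per spot, deposited as 0 or 1, that mark spots well above background, saturated, or uneven. The deposited value table of the whole series held a log10 ratio for 98 arrays. In all 98 columns it equalled the scanner files' log ratio turned to own RNA over reference, within 5e-06. Its column medians lay between -0.019 and 0, so the arrays had not been centred further; scale and direction were thereby known. Whether any other filter was applied is not given in the sources used here.

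Mean signals were corrected with normexp (offset 50) against the local background, using R 4.3.3 and limma 3.58.1. Log2 ratios were normalized within each array by loess, in which control spots had weight 0, and spots marked as uneven were left out. Saturated spots were kept. Each ratio was turned to own RNA over reference by the dyes in the labels, spots of 1 probe were averaged, and the 2 arrays of an extract were averaged into 1 value, so a dye effect cancels. Over the 49 extracts, the 2 arrays of a pair correlated at 0.9415 or higher, with a median of 0.974 across probes. A fold change is a difference of these log2 ratios, and a log2 difference of 1 is a 2-fold change.

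The array held 43790 spots, of which 2256 were controls, and 41174 different probes. Of the probes, 20177 carried only the name in the file, and the others were matched to RefSeq symbols, 11450 by accession and 2296 by symbol. In all, 15968 genes had a RefSeq symbol and 4186 of them had more than 1 probe. A gene was represented by its probe with the highest mean intensity over all arrays and channels, and probes without a symbol were kept as features of their own. A feature was tested when it was well above background in the own-RNA channel on at least 50% of the arrays of at least 1 arm, which left 32445 features (15169 with a symbol) in the tumor comparisons and 32391 (15136 with a symbol) among normal lungs. On single arrays, 72.3% to 92.8% of probes were well above background in the own-RNA channel, with a median of 87.35%. The number of arrays limits the precision. A probe saturated on every array of an arm has only a bound there. For Scgb3a2, the 1 named gene of this kind, the bound from the own-RNA channel exceeded the fold of the fitted log ratios, so no bound is printed and the fitted change is given with its saturated arrays.

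Comparisons used limma (lmFit, eBayes) with Benjamini-Hochberg adjustment over all features. A feature was called at an adjusted p under 0.05 and a change of at least 2-fold. HER2 tumors and KRAS tumors were each compared with the 13 normal lungs, and with each other, with only the extracts of the compared arms in the model. The 129SvEv lungs were compared with the C57Bl6 lungs, and the chimera lungs with the mean of those strains, in 1 model over the 13 normal lungs. The words rose and fell are used of genes past the adjusted p, whether or not they reached 2-fold. The designs, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes with a symbol (5 and 5 between normal lungs), all members of the list of driver and tumor suppressor genes, and up to 4 members of each list with the largest change past the adjusted p. The 10 largest rises and falls of the tumor comparisons also had to be well above background on at least 1 array of each arm. The other named genes did not have to be.

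There were 39 gene lists. The 21 lists of cell type markers covered AT2 alveolar type 2, AT1 alveolar type 1, club, ciliated, basal and squamous, neuroendocrine and gastrointestinal epithelial cells, endothelium, fibroblasts, smooth muscle, cardiac muscle, adipocytes, mesothelium, red blood cells, alveolar macrophages, monocytes and macrophages, T, NK and B cells, neutrophils, and mast cells. The 15 pathway lists covered the cell cycle, ERK output, ERBB receptors and ligands, immediate early genes, interferon response, MHC class II, chemokines, proteases, glycolysis and hypoxia, cholesterol synthesis, fatty acid synthesis, the unfolded protein response, NRF2 targets, p53 targets, and embryonic and imprinted genes. The 3 check lists held circadian, sex-linked, and driver and tumor suppressor genes. The first 36 lists were tested with limma camera at a preset correlation of 0.01, adjusted over 36 lists and 3 comparisons together, and again with a correlation estimated from the data. In all, 39 of the 108 tests passed at the preset correlation, and 0 passed with the estimated one. Camera sets a list against all other features. It does not ask whether a list moved in each tumor, so the number of tumors whose list score (the mean log2 ratio of the measured members) lay outside the range of the 13 normal lungs is given beside it. This is done for lists that passed against normal lung and for some that did not.

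Feature extraction times in the file headers put the arrays into 5 sessions separated by over 24 hours. A session is thus a period in which that software was run, and times of scanning or hybridisation were not used. Each slide held 1 array, so slide was no batch. Session 1 held HER2 tumors 1 to 9; session 2 held the other 9 HER2 tumors and 1 normal lung of unspecified strain; session 3 held KRAS tumors 1 to 10; session 4 held the other 8 KRAS tumors and 2 unspecified normal lungs; session 5 held the other 10 normal lungs. Session was fitted as a fixed block in each comparison with normal lung, which then rests on the 1 or 2 normal lungs that shared a session with the tumors. Between the tumor models, session was fitted as a random block (duplicateCorrelation), and, chosen after seeing the data, as a fixed block linked through the unspecified normal lungs.

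The steps were tested on simulated data with 200 changed genes, 50 for each size. Of genes changed by 1.5 on the log2 scale, 98% were called for HER2 tumors against normal lung (32445 features), 100% for KRAS tumors against normal lung (32445), 100% for HER2 against KRAS tumors (32445), 96% for 129SvEv against C57Bl6 lung (32391) and 100% for the chimera comparison (32391). Of genes changed by exactly the 2-fold limit, 50%, 48%, 46%, 52% and 60% were called in the same order. Called among the unchanged features were 0, 1, 0, 0 and 1. In a separate simulation of HER2 tumors only the endothelium list was shifted. Camera recovered it, and 0 of the other lists passed. Genes were drawn independently of each other there, so this does not show how the list test behaves when genes of a list are correlated.

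HER2 tumors 8 and 9 were the closest extracts. Across probes they correlated at 0.9932, and their difference was 0.9216 times the technical noise. Between their 4 arrays, 987 of 36047 probes differed, against a median of 12146 over pairs of HER2 tumors, and Cfd fell by 3.47 on the log2 scale from the first to the second. These arrays cannot show whether they come from separate tumors or animals. They were kept as 2 samples because the labels name them so, and counts without HER2 tumor 9 were computed. Other alternatives were the scanner software's log ratios, the deposited value table, median centring, scaling between arrays, looser and stricter filters, another probe per gene, single dyes, array weights, other thresholds, subsets of the normal lungs, and single extracts left out.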

Results

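RNA from 36 mouse lung tumors and 13 normal lungs was set against 1 common reference RNA on 98 arrays, 2 for each extract. The tumors came from a mouse model named for a mutant HER2 (18 extracts) and from one named for a mutant KRAS (18 extracts). HER2, encoded by Erbb2, is a growth factor receptor, and KRAS is a small GTPase that passes signals from such receptors to the ERK kinases. The series asks how the tumors of each model differ from normal lung, and the design allows the models to be compared with each other. Normal lungs of C57Bl6 (3) and 129SvEv mice (3), of uninduced HER2 chimeras (4) and of unspecified strain (3) also allow the strains and the uninduced chimeras to be compared. All values are log2 ratios to the reference RNA, and changes are given on the log2 scale ± SE unless a fold is named. Beside a gene, a count of 18 tumors gives those beyond the mean of the other group unless all normal lungs are named, and beside a list those outside the range of the normal lungs.

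The drivers were read first, since they check the labels. Kras lay at 2.92 ± 0.38 (SD, n = 18) in KRAS tumors, at -1.83 ± 0.23 (n = 18) in HER2 tumors and at -2.01 ± 0.42 (n = 13) in normal lungs. The lowest KRAS tumor (1.71) exceeded the highest of all other extracts (-1.35). It rose by 4.94 ± 0.14 in KRAS tumors against normal lung, or 30.7-fold (adjusted p = 6.18e-22, 18 of 18 tumors above all normal lungs; 4.72 with session as a block). Its probe was saturated on 34 of the 36 arrays of KRAS tumors, so the rise is understated. A second probe gave 3.98 in KRAS tumors against -1.55 in normal lungs, while another probe of the gene gave 0.76 against 0.5. Erbb2, measured by 1 probe, lay at 1.03 ± 0.23 in HER2 tumors, 0.83 ± 0.21 in KRAS tumors and 0.16 ± 0.14 in normal lungs. It rose in both models, by 0.87 ± 0.07 in HER2 tumors (adjusted p = 1.75e-12, 18 of 18) and by 0.67 ± 0.07 in KRAS tumors (adjusted p = 4.03e-10, 18 of 18). The labels do not give the species or part of the gene that the HER2 model carries, so this probe does not check the HER2 label.

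HER2 tumors were compared with normal lung to ask what the HER2 model changes. Dlk1, an imprinted Notch-family protein of fetal tissue, rose 68-fold (6.09 ± 0.14, adjusted p = 1.1e-25, 18 of 18 tumors above all 13 normal lungs; 6.11 with session as a block), with its probe saturated on 20 of 36 tumor arrays. Gkn2, a gastrokine of the stomach lining, rose 41.5-fold, Kng1, the precursor of bradykinin, 37.4-fold, and Areg, the EGFR ligand amphiregulin, 22.3-fold (4.48 ± 0.12, adjusted p = 3.32e-24, 18 of 18). Only 5 of 26 normal lung arrays measured Gkn2 well above background and 16 of 26 Kng1, so their folds rest on a baseline near background. The largest fall was that of Ogn, the matrix proteoglycan osteoglycin, at 33.4-fold lower (-5.06 ± 0.23, adjusted p = 1.64e-18, 18 of 18).

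In all, 2710 of 32445 features were called, 1026 higher and 1684 lower in HER2 tumors. Of these, 1704 had a gene symbol (664 higher, 1040 lower). Without the fold requirement, 22701 features passed the adjusted p. The other leading rises were Fetub, a protease inhibitor of plasma (4.19 ± 0.16), Arc, an immediate early gene of neurons (3.96 ± 0.23), and St8sia6, a sialyltransferase (3.84 ± 0.12). They also included Atp13a4, a P5-type ATPase (3.78 ± 0.12), Ankrd22 (3.75 ± 0.12) and Fbp2, a muscle form of fructose bisphosphatase (3.62 ± 0.21). The other leading falls were Cfd, the adipocyte protease adipsin (-4.7 ± 0.51), Fibin (-4.66 ± 0.24), the caveolar protein Cavin2 (-4.47 ± 0.19), and the matrix proteins Efemp1 (-4.47 ± 0.23) and Pcolce2 (-4.25 ± 0.27). They also included the glutamate receptor Gria1 (-4.24 ± 0.13), thrombomodulin, encoded by Thbd (-4.2 ± 0.26), the monooxygenase Fmo3 (-4.03 ± 0.19) and Xist, the RNA that silences 1 X chromosome in females (-4.01 ± 0.64). A second Gria1 probe gave only -0.74. With session as a block, Xist was -3.62 ± 1.63 with adjusted p = 0.0842, while the other 19 of these 20 genes stayed past the adjusted p in the same direction.

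Of 13 markers of alveolar type 2 cells, which make surfactant, 11 rose, 2 fell and 0 did not pass, including Lpcat1, a surfactant lipid enzyme (1.41 ± 0.08), and Lamp3, a lamellar body protein (1.32 ± 0.08). The list mean was 0.64 (camera adjusted p = 0.00105, 18 of 18 tumors above all normal lungs), with adjusted p = 0.497 with an estimated correlation. Of 6 markers of type 1 cells, the thin gas exchange cells, 1 rose and 5 fell, such as Igfbp2 (-2.84 ± 0.16) and Pdpn, podoplanin (-1.01 ± 0.09), and the list, at a mean of -0.83, missed the threshold (adjusted p = 0.0588; 0.0365 with session as a block). All 11 ciliated cell markers fell, with a mean of -1.68 (adjusted p = 1.16e-05, 18 of 18 below; adjusted p = 0.497 with an estimated correlation), among them Tekt1, a tektin of the axoneme (-2.28 ± 0.2), and the microtubule protein Tppp3 (-2.14 ± 0.18). Of 11 club cell markers, 1 rose, 7 fell and 3 did not pass (adjusted p of the list = 0.0588). Scgb3a2, a secretoglobin of club cells, was saturated on all 26 arrays of normal lung, and its fitted change was -2.19 ± 0.38 (adjusted p = 6.36e-06, 18 of 18 below the mean of the normal lungs and 16 below all of them). It was -2.18 ± 1.11 with session as a block, where the larger SE ended the call (adjusted p = 0.126).

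Of 18 endothelial markers, 17 fell and 1 rose (mean -1.38, adjusted p = 8.99e-06), including Calcrl, a receptor of adrenomedullin (-3.59 ± 0.26), and Flt1, a VEGF receptor (-2 ± 0.08). Of 14 fibroblast markers, 12 fell, 1 rose and 1 did not pass (mean -1.25, adjusted p = 0.00413), such as Pdgfra (-2.69 ± 0.21), a receptor of lung mesenchyme. Of 10 smooth muscle markers, 9 fell and 1 rose (mean -1.2, adjusted p = 0.00484), led by Cnn1, calponin (-3.42 ± 0.33). All 18 tumors lay below all normal lungs for each of these lists. With an estimated correlation these 3 lists lost their calls: endothelium had adjusted p = 0.497 with an estimated correlation, fibroblasts adjusted p = 0.516 with an estimated correlation, and smooth muscle adjusted p = 0.537 with an estimated correlation. Of 10 cardiac muscle markers, 8 fell, 1 rose and 1 did not pass (mean -2.05, adjusted p = 0.00579), such as Myl7, an atrial myosin light chain (-3.89 ± 0.43), and the troponin Tnnt2 (-3.49 ± 0.27). All 7 adipocyte markers fell (mean -2.06, adjusted p = 0.00579), such as Adipoq, adiponectin (-2.72 ± 0.23), and both of these lists had adjusted p = 0.497 with an estimated correlation. Of 4 mesothelial markers, 3 fell and 1 did not pass (adjusted p of the list = 0.0668).

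Of 11 alveolar macrophage markers, 10 rose and 1 did not pass (mean 0.98, adjusted p = 0.00169, 17 of 18 tumors above; adjusted p = 0.497 with an estimated correlation), such as the scavenger receptors Marco (2.12 ± 0.24) and Msr1 (1.41 ± 0.1). All 9 NK and cytotoxic cell markers fell (mean -0.91, adjusted p = 0.0012, 18 of 18 below; adjusted p = 0.497 with an estimated correlation), led by the protease Gzma (-2.73 ± 0.22). Of 10 MHC class II genes, which present antigen, 8 rose and 2 fell (mean 0.55, adjusted p = 0.0428, 11 of 18 above; adjusted p = 0.635 with an estimated correlation), among them Cd74, the invariant chain (0.95 ± 0.08). Of 16 interferon response genes, 12 fell, 1 rose and 3 did not pass (mean -0.88, adjusted p = 0.00868, 16 of 18 below; adjusted p = 0.671 with an estimated correlation), such as Ifit1 (-1.68 ± 0.21) and Rsad2 (-1.55 ± 0.23), antiviral proteins.

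Of 28 cell cycle genes, 24 rose, 1 fell and 3 did not pass (mean 0.71, adjusted p = 0.000207, 12 of 18 above all normal lungs; adjusted p = 0.635 with an estimated correlation), such as the mitotic genes Birc5, survivin (1.29 ± 0.2), and Mki67 (1.1 ± 0.15). Of 16 ERK output genes, 12 rose, 2 fell and 2 did not pass (mean 0.82, adjusted p = 0.000521, 18 of 18; adjusted p = 0.415 with an estimated correlation), such as the transcription factors Etv4 (2.62 ± 0.11) and Myc (1.4 ± 0.11) and the receptor kinase Epha2 (1.76 ± 0.07). Of 13 ERBB receptors and ligands, 10 rose, 1 fell and 2 did not pass (mean 1.03, adjusted p = 0.00228, 18 of 18; adjusted p = 0.376 with an estimated correlation). The ligands Areg and Ereg, epiregulin (2.94 ± 0.15), led the rises, and the receptor Egfr fell (-1.95 ± 0.14). Of 19 glycolysis and hypoxia genes, 17 rose, 1 fell and 1 did not pass (mean 1.28, adjusted p = 1.16e-05, 18 of 18; adjusted p = 0.497 with an estimated correlation), such as the hypoxia-induced hydroxylase Egln3 (2.75 ± 0.27), lactate dehydrogenase Ldha (2.12 ± 0.07) and phosphofructokinase Pfkl (2.11 ± 0.12). Among the tumor suppressors, Cdkn2b, a cyclin kinase inhibitor, rose by 0.88 ± 0.08, while Rb1 (-0.93 ± 0.09), Pten (-0.7 ± 0.07), Cdkn2a (-0.61 ± 0.07) and Stk11 (-0.48 ± 0.03) fell. Cdkn2a was 0.18 ± 0.13 with session as a block (adjusted p = 0.312). Other probes gave smaller falls for Pten (-0.25 to -0.12), Egfr (-0.98 to -0.48), Calcrl (-1.43), Flt1 (-1.63 to -0.03) and Rsad2 (-0.54 to -0.49). The Cdkn2a probe was dim in HER2 tumors, at 6.26 on the log2 scale in the own-RNA channel, though well above background on 36 of 36 arrays. Kras (0.18 ± 0.11, adjusted p = 0.152) and Trp53 (0.03 ± 0.12, adjusted p = 0.846, with the sign turned under median centring, scaling and Cy5 arrays alone) did not pass.

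The remaining lists did not pass in HER2 tumors, though some scores lay outside the range of the normal lungs in most tumors. All 18 tumors lay below it for T cells and for mast cells and basophils. All 18 lay above it for gastrointestinal epithelium and for embryonic genes, 17 for p53 targets and 16 for proteases. Monocytes and macrophages had 8 members up, 2 down and 3 not past (adjusted p = 0.0819), T cells 1, 7 and 4 (0.051), mast cells and basophils 0, 4 and 3 (0.0509), and red blood cells 1, 2 and 3 (0.621). B cells had 4, 4 and 1 (0.954, with a mean of -0.22 against a test direction of up), neutrophils 2, 2 and 6 (0.934), basal and squamous epithelium 3, 3 and 3 (0.995), neuroendocrine cells 2, 5 and 2 (0.465) and gastrointestinal epithelium 8, 1 and 6 (0.127). The same counts were 6, 2 and 4 for immediate early and heat shock genes (0.556), 12, 5 and 5 for chemokines (0.465), 11, 5 and 0 for proteases (0.187), and 5, 5 and 6 for cholesterol synthesis (0.94). They were 6, 4 and 1 for fatty acid synthesis (0.634), 11, 4 and 1 for the unfolded protein response (0.115), 10, 5 and 2 for NRF2 targets (0.132), 9, 2 and 2 for p53 targets (0.0766) and 6, 3 and 2 for embryonic and imprinted genes (0.219). In the last list the mean was 1.15 and the median 0.16, and its largest rises were Dlk1 and the progenitor factor Sox9 (3.11 ± 0.33). The mean and median of basal epithelium differed in sign (-0.14 and 0.01, with the test pointing up), and the median of B cells was 0. Of 12 circadian genes, 2 rose, 4 fell and 6 did not pass. Adjusted over the list alone, the counts were the same in all lists except club cells (8 fell), gastrointestinal epithelium (7 rose) and circadian genes (1 rose). Of the 8 driver and tumor suppressor genes, 2 rose, 4 fell and 2 did not pass.

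Session limits this comparison, since only 1 normal lung shared a session with HER2 tumors. With session as a block, 3033 features were called, 2242 of them among the 2710 in the same direction. Within session 2 alone 2922 were called. Of the 168 named genes past the adjusted p, 134 stayed past it with the block. Of the 15 lists, 11 held with the block. Their blocked means were 0.44 for type 2 cells, -1.67 for ciliated cells, -1.81 for endothelium, -1.6 for smooth muscle, -2.53 for cardiac muscle, -3.39 for adipocytes and -1.14 for NK cells. Those of the rising pathway lists were 1.06 for the cell cycle, 0.96 for ERK output, 1.12 for ERBB genes and 1.43 for glycolysis. The block ended the calls of fibroblasts (mean -1.11, adjusted p = 0.125), alveolar macrophages (0.86, 0.0552), interferon response (-0.78, 0.207) and MHC class II (0.36, 0.348). It brought type 1 cells (-1.12, 0.0365), NRF2 targets (0.24, 0.0379), p53 targets (0.52, 0.0378) and embryonic genes (1.37, 0.0331) past the threshold. With an estimated correlation and no block, camera gave these lists adjusted p = 0.497, 0.605, 0.497 and 0.577. The block rests on unspecified lung 1, which lay at an end of the normal lungs in several scores. It was highest for type 1 cells (3.318), endothelium (4.534) and adipocytes (4.303). It was lowest for the cell cycle (-3.35), ERK output (-0.379), p53 targets (-0.46) and embryonic genes (-1.348). Its NRF2 (-0.069) and type 2 (3.425) scores lay inside the range of the others. For the lists at an end, the block cannot part session from this lung's own level.

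KRAS tumors were compared with normal lung to ask the same of the KRAS model. Among the rises were those of Dlk1 (5.09 ± 0.44, 34.1-fold, adjusted p = 3.81e-11, 18 of 18), saturated on 12 of 36 tumor arrays, and of Kras itself, saturated on 34. Kng1 (3.73 ± 0.33), Gkn2 (3.62 ± 0.44), Fetub (3.59 ± 0.26) and Areg (3.5 ± 0.2, 11.3-fold, adjusted p = 2.28e-14, 18 of 18) also rose. Eif2s3y, a Y-linked translation factor, rose by 4.12 ± 0.61 (adjusted p = 8.57e-07, 16 of 18 above the mean of the normal lungs and 4 above all of them), but was 0.58 ± 1.15 with session as a block (adjusted p = 0.749), and 4 of 26 normal lung arrays measured it well above background. The largest falls were those of Cfd (-5.17 ± 0.49, 36.1-fold, adjusted p = 2.51e-10, 18 of 18 below the mean of the normal lungs and 16 below all of them) and Ogn (-4.71 ± 0.45).

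In all, 2033 of 32445 features were called, 691 higher and 1342 lower in KRAS tumors. Of these, 1277 had a symbol (429 higher, 848 lower), and 19434 passed the adjusted p alone. St8sia6 (3.29 ± 0.18), Ankrd22 (3.26 ± 0.25) and Atp13a4 (3.11 ± 0.2) completed the 10 largest rises. The other large falls were Fibin (-4.31 ± 0.42), Myl7 (-4.18 ± 0.41), Sln, sarcolipin of the heart atrium (-3.99 ± 0.36), the carbonic anhydrase Car3 of fat and muscle (-3.94 ± 0.39), and Thbd (-3.91 ± 0.44). Also among them were Cnn1 (-3.89 ± 0.39), Fmo3 (-3.78 ± 0.43) and the cytochrome P450 Cyp2a4 (-3.77 ± 0.47). Other probes of Sln, Car3 and Cyp2a4 gave only -0.08, -1.21 and -1.6. The spread between KRAS tumors was wide: on the first principal component they ranged from -47.7 to 58.2, HER2 tumors from -59.5 to -13.9 and normal lungs from 65.3 to 78.7. KRAS tumor 1 lay nearest the normal lungs, and 2219 features were called without it.

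**Figure D1:**
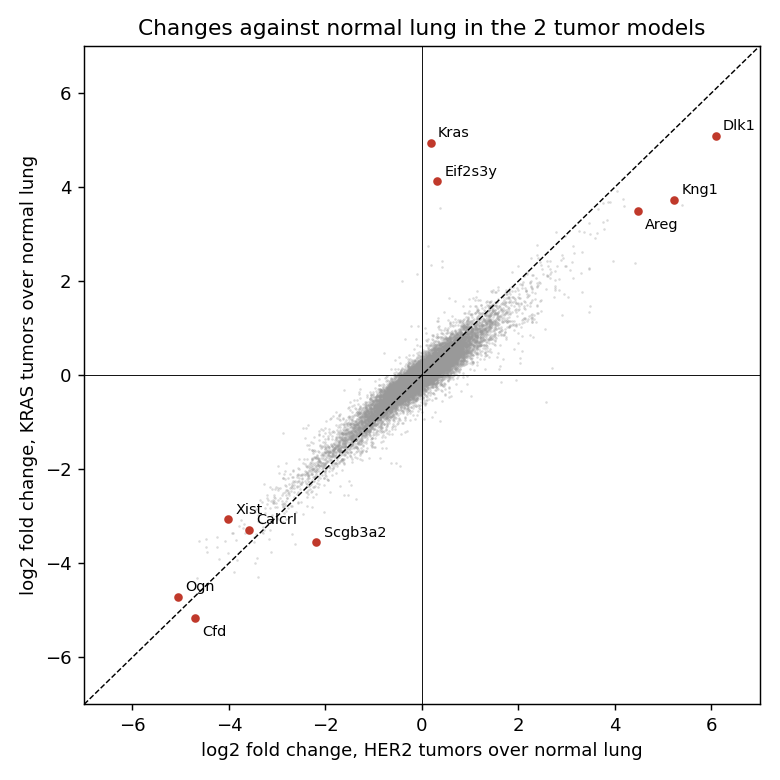
Each grey point is a feature, placed by its log2 fold change over normal lung in HER2 tumors (x axis) and KRAS tumors (y axis), with named genes in red and a dashed line where both are equal. The points lie along the line (r = 0.9406 across features), and Kras (0.18 and 4.94) and Eif2s3y stand far above it.

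Alveolar, airway and stromal markers moved as follows in KRAS tumors. Of 13 type 2 markers, 11 rose and 2 fell (mean 0.54, adjusted p = 0.000478, 17 of 18 tumors above all normal lungs), such as the surfactant protease Napsa (1.01 ± 0.15) and the mucin Muc1 (0.77 ± 0.07). Of 6 type 1 markers, 5 fell and 1 did not pass (mean -0.87, adjusted p = 0.00855, 17 of 18 below), such as Igfbp2 (-2.2 ± 0.29) and Emp2 (-1.19 ± 0.14). Of 11 club cell markers, 8 fell and 3 did not pass (mean -1.42, adjusted p = 0.00301, 16 of 18 below), such as the GABA receptor subunit Gabrp (-2.78 ± 0.37). The fitted change of Scgb3a2 was -3.55 ± 0.68 (adjusted p = 3.87e-05, 14 of 18), with saturation on all 26 arrays of normal lung and on 4 of KRAS tumors. All 11 ciliated markers fell (mean -1.7, adjusted p = 3.51e-05, 17 of 18 below), such as Foxj1, the master regulator of motile cilia (-2.49 ± 0.38). All 18 endothelial markers fell (mean -1.35, adjusted p = 3.95e-07, 18 of 18), such as Calcrl (-3.29 ± 0.4) and Flt1 (-2.12 ± 0.24). Each of these 5 lists had adjusted p = 0.497 with an estimated correlation.

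Of 14 fibroblast markers, 11 fell, 1 rose and 2 did not pass (mean -1.14, adjusted p = 0.0031, 18 of 18 below; adjusted p = 0.499 with an estimated correlation), such as the mesenchymal factor Tcf21 (-2.49 ± 0.28). Of 10 smooth muscle markers, 9 fell and 1 did not pass (mean -1.35, adjusted p = 6.22e-05, 17 of 18), such as the myosin Myh11 (-1.68 ± 0.19). Of 10 cardiac markers, 9 fell and 1 did not pass (mean -2.28, adjusted p = 4.71e-05, 17 of 18). All 7 adipocyte markers fell (mean -2.14, adjusted p = 0.000665, 17 of 18), such as Adipoq (-2.79 ± 0.28). Of 4 mesothelial markers, 3 fell and 1 did not pass (mean -1.46, adjusted p = 0.0187, 15 of 18), such as Msln, mesothelin (-2.05 ± 0.3), and Upk3b (-1.92 ± 0.21). The smooth muscle, cardiac, adipocyte and mesothelial lists each had adjusted p = 0.497 with an estimated correlation.

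Immune and growth lists in KRAS tumors passed as follows. All 9 NK and cytotoxic markers fell (mean -0.76, adjusted p = 0.00172, 16 of 18 below; adjusted p = 0.537 with an estimated correlation), such as Gzma (-2.11 ± 0.31). Of 16 interferon genes, 12 fell and 4 did not pass (mean -0.81, adjusted p = 0.00169, 14 of 18 below; adjusted p = 0.613 with an estimated correlation), such as Ifit1 (-1.52 ± 0.23). Of 10 MHC class II genes, 8 rose, 1 fell and 1 did not pass (mean 0.66, adjusted p = 0.0011, 17 of 18 above; adjusted p = 0.497 with an estimated correlation), such as H2-DMb1 (1.19 ± 0.09) and Ciita, the transactivator of the class (1.18 ± 0.09). Of 28 cell cycle genes, 26 rose, 1 fell and 1 did not pass (mean 0.66, adjusted p = 9.49e-06, 9 of 18 above all normal lungs; adjusted p = 0.552 with an estimated correlation), such as Birc5 (1.38 ± 0.2) and thymidylate synthase Tyms (1.07 ± 0.13). Of 16 ERK output genes, 11 rose, 2 fell and 3 did not pass (mean 0.58, adjusted p = 0.00196, 17 of 18), such as Etv4 (2.11 ± 0.19) and the feedback inhibitor Spry2 (1.34 ± 0.15). Of 13 ERBB genes, 9 rose, 1 fell and 3 did not pass (mean 0.64, adjusted p = 0.00246, 17 of 18), such as the ligands Ereg (1.72 ± 0.14) and Btc (1.18 ± 0.09), while Egfr fell (-1.71 ± 0.21). The ERK and ERBB lists each had adjusted p = 0.497 with an estimated correlation. Of 19 glycolysis genes, 16 rose and 3 did not pass (mean 0.85, adjusted p = 0.000654, 18 of 18; adjusted p = 0.552 with an estimated correlation), such as hexokinase Hk2 (1.57 ± 0.13) and Ldha (1.47 ± 0.11). Cdkn2b rose (0.5 ± 0.11), Rb1 (-0.77 ± 0.13), Pten (-0.61 ± 0.06), Stk11 (-0.41 ± 0.04) and Cdkn2a (-0.31 ± 0.1) fell, and Trp53 did not pass (0.09 ± 0.08, adjusted p = 0.332). Other probes gave smaller falls for Pten (-0.21 to -0.01), Egfr (-0.85 to -0.45), Calcrl (-1.34) and Flt1 (-1.75 to -0.1). With session as a block, Cdkn2b (0.33 ± 0.24) and Cdkn2a (-0.21 ± 0.11) no longer passed, with adjusted p = 0.306 and 0.141. The Cdkn2a probe was dim in KRAS tumors too (6.33), and well above background on 29 of 36 arrays.

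The other lists did not pass in KRAS tumors, though some scores lay outside the range of the normal lungs in most tumors. All 18 tumors lay above it for embryonic genes and 13 for p53 targets. Below it lay 17 for mast cells, and 14 for T cells with 1 above. Alveolar macrophage markers had 7 members up, 1 down and 3 not past (adjusted p = 0.127), monocytes and macrophages 7, 2 and 4 (0.115), T cells 1, 6 and 5 (0.11) and mast cells 1, 4 and 2 (0.131). Red blood cells had 0, 1 and 5 (0.383), B cells 2, 1 and 6 (0.767), neutrophils 0, 5 and 5 (0.262), basal epithelium 3, 4 and 2 (0.75), neuroendocrine cells 1, 3 and 5 (0.359) and gastrointestinal epithelium 6, 2 and 7 (0.198). The counts were 6, 2 and 4 for immediate early genes (0.584), 10, 4 and 8 for chemokines (0.491), 8, 5 and 3 for proteases (0.529) and 2, 9 and 5 for cholesterol synthesis (0.149). They were 6, 2 and 3 for fatty acid synthesis (0.54), 6, 4 and 6 for the unfolded protein response (0.75), 8, 4 and 5 for NRF2 targets (0.248), 8, 2 and 3 for p53 targets (0.0668), 6, 2 and 3 for embryonic genes (0.372) and 0, 4 and 8 for circadian genes. The mean and median differed in sign for B cells (-0.14 and 0.05, with the test pointing up), basal epithelium (-0.28 and 0.01, down) and the unfolded protein response (0.06 and -0.01, up). Adjusted over the list alone, the counts were the same except for cholesterol synthesis (3 rose). Of the 8 driver and tumor suppressor genes, 3 rose, 4 fell and 1 did not pass.

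With session as a block, which rests on 2 normal lungs, 2289 features were called, 1739 of them among the 2033 in the same direction; within session 4 alone 2227 were called. Of 165 named genes past the adjusted p, 119 stayed past it, and all 17 lists held. The block also brought T cells (-0.6, adjusted p = 0.0163), mast cells (-0.58, 0.038) and p53 targets (0.37, 0.0293) past the threshold. With an estimated correlation and no block, camera gave these lists adjusted p = 0.671, 0.497 and 0.537. The blocked means were 0.61 for type 2 cells, -1.06 for type 1, -1.62 for club, -1.79 for ciliated cells, and -1.48 for endothelium. They were -1.1 for fibroblasts, -1.58 for smooth muscle, -2.73 for cardiac muscle, -1.88 for adipocytes, and -1.62 for mesothelium. The others were -0.88 for NK cells, -0.98 for interferon, 0.38 for MHC class II, 0.7 for the cell cycle, 0.81 for ERK output, 0.74 for ERBB genes and 0.79 for glycolysis.

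**Figure D2:**
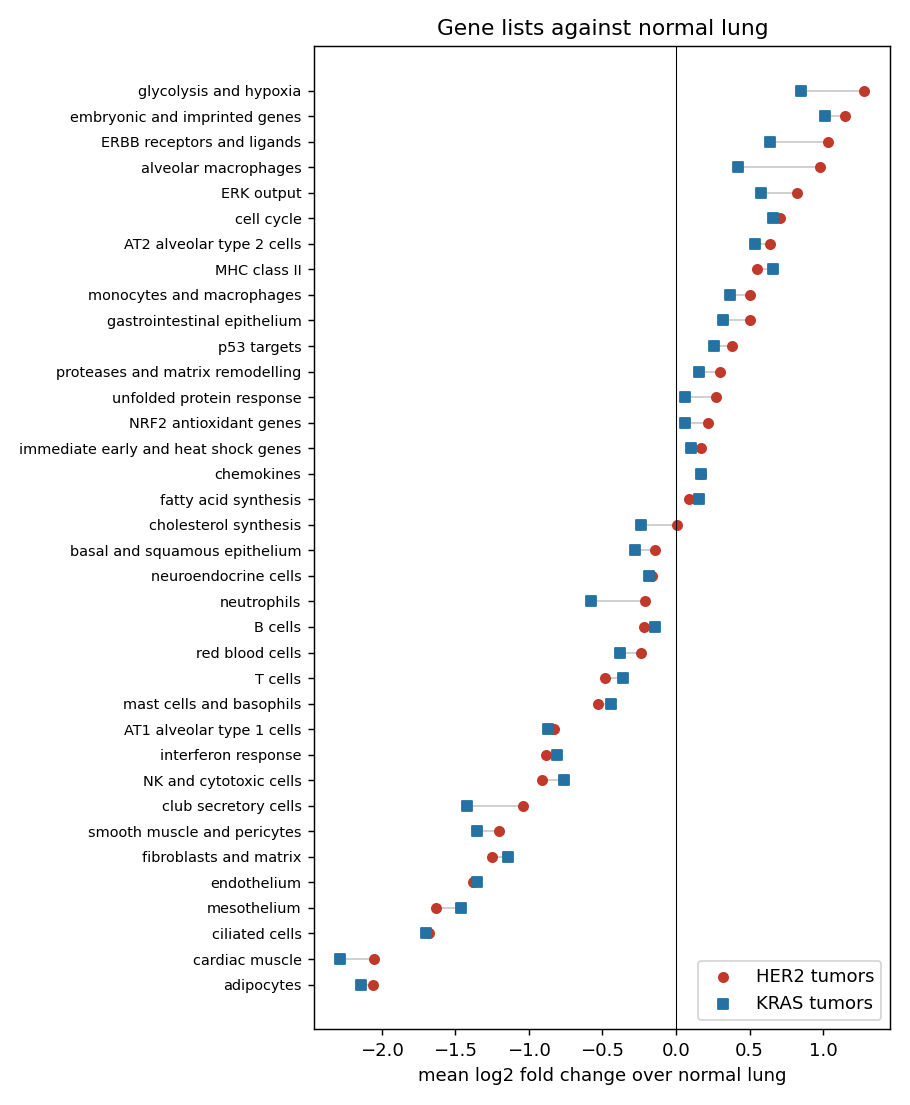
Mean log2 fold change over normal lung of the measured members of each cell type or pathway list, for HER2 tumors (red circles) and KRAS tumors (blue squares), with lists ordered by the HER2 value. Adipocytes (-2.06 and -2.14) and cardiac muscle (-2.05 and -2.28) lie lowest, glycolysis and hypoxia highest for HER2 tumors (1.28), and embryonic and imprinted genes highest for KRAS tumors (1.01).

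Most of the changes were common to both models. Of the called features, 1839 were called in both in the same direction, 585 higher and 1254 lower, and 0 in opposite directions. The shared features are 90.5% of the KRAS calls and 67.9% of the HER2 calls. Independent lists would share 21.9 higher and 69.7 lower features. Because both comparisons use the same normal lungs, 100 sets of unchanged groups were simulated, each with 1 simulated normal group common to both comparisons. These shared 0 called features. Unchanged features drawn independently are almost never called at 2-fold, so this 0 was nearly fixed in advance. It does not measure how far common normal lungs raise the overlap. With the normal lungs split between the comparisons (7 and 6), 1826 features were shared, or 1774 with the parts exchanged. The split does not remove session. Most normal lungs of both parts were in session 5, which held no tumors, so a shift of that session would enter both comparisons. The overlap was not computed with session as a block. Across features, which are not independent replicates, the fold changes correlated at r = 0.9406, against 0.4783 in the simulation and 0.9363 with the normal lungs split. Their covariance was 0.2889 against 0.002919 simulated, a difference of 0.286, and the slope of KRAS changes on HER2 changes was 0.806.

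The models were compared directly to ask where they differ. HER2 tumors had more transcript of Procr, the endothelial protein C receptor (2.13 ± 0.19, 4.37-fold, adjusted p = 1.64e-10, 18 of 18 above the KRAS mean), of the neutrophil surface protein Cd177 (2.03 ± 0.17), and of the EGFR ligand Epgn, epigen (1.68 ± 0.18). KRAS tumors had more Kras (-4.75 ± 0.1 for HER2 against KRAS, 27-fold, adjusted p = 4.96e-29, 18 of 18), by a probe saturated on 34 of 36 KRAS arrays, of the kinase gene Sbk1 (-2.63 ± 0.23), and of the Y-linked Eif2s3y (-3.81 ± 0.5) and Ddx3y, an RNA helicase (-2.25 ± 0.26).

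In all, 88 of 32445 features were called, 64 higher and 24 lower in HER2 tumors. Of these, 60 had a symbol (45 higher, 15 lower), and 12033 passed the adjusted p alone. The other leading genes higher in HER2 tumors were Tmem40 (2.05 ± 0.23), the fibrinogen chain Fgg (1.79 ± 0.28), Susd3 (1.77 ± 0.19) and Gkn2 (1.76 ± 0.4). They were followed by the serpin Serpinb5 (1.63 ± 0.29), Atp13a5 (1.57 ± 0.12) and involucrin, Ivl, of squamous epithelium (1.57 ± 0.18). The other genes lower in HER2 tumors were the G protein subunit Gna15 (-1.89 ± 0.2), the chitinase Chia1 (-1.34 ± 0.37), Lrrn3 (-1.31 ± 0.3), Esm1, a secreted endothelial proteoglycan (-1.3 ± 0.27), Cys1 (-1.28 ± 0.12) and the cadherin Cdh16 (-1.27 ± 0.25). Other probes gave only 0.45 for Susd3, 0.16 for Atp13a5 and -0.3 for Lrrn3. Cdkn2b rose (0.38 ± 0.08) and Cdkn2a fell (-0.3 ± 0.07, adjusted p = 0.00107), but the latter turned to 0.22 with the scanner software's log ratios (adjusted p = 0.0281). Erbb2 was higher by 0.2 ± 0.07 (adjusted p = 0.0273, 12 of 18 above the KRAS mean), and 0.19 ± 0.1 with session as a random block, where the larger SE ended the call (adjusted p = 0.206). Trp53 (-0.06 ± 0.1), Pten (-0.09 ± 0.06), Rb1 (-0.16 ± 0.12) and Stk11 (-0.07 ± 0.04) did not pass.

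Of the 36 lists, 7 passed between the models, each higher in HER2 tumors. Of 11 alveolar macrophage markers, 10 rose and 1 did not pass (mean 0.56, adjusted p = 0.00112; adjusted p = 0.499 with an estimated correlation), such as Marco (0.99 ± 0.19) and Krt79 (1.06 ± 0.27). Of 13 ERBB genes, 7 rose and 6 did not pass (9 rose adjusted over the list alone; mean 0.39, adjusted p = 0.00492), such as Ereg (1.22 ± 0.18) and Areg (0.98 ± 0.15). Of 16 ERK output genes, 9 rose and 7 did not pass (mean 0.25, adjusted p = 0.0062), such as Phlda1 (0.79 ± 0.11) and cyclin D1, Ccnd1 (0.57 ± 0.09). Of 16 cholesterol synthesis genes, 10 rose and 6 did not pass (11 rose adjusted over the list alone; mean 0.25, adjusted p = 0.000268), such as Dhcr24 (0.69 ± 0.13) and Mvd (0.52 ± 0.06). The ERBB, ERK and cholesterol lists each had adjusted p = 0.497 with an estimated correlation. Against normal lung, the cholesterol list had a mean of 0.01 in HER2 tumors and -0.24 in KRAS tumors, and passed in neither. Of 18 KRAS tumors, 12 lay below all normal lungs and 2 above in its score. Its difference between the models thus came with lower levels in KRAS tumors, without a rise over normal lung in HER2 tumors. Of 19 glycolysis genes, 9 rose, 1 fell and 9 did not pass (10 rose adjusted over the list alone; mean 0.43, adjusted p = 0.000521; adjusted p = 0.537 with an estimated correlation), such as Pgk1 (0.92 ± 0.19) and the pyruvate kinase Pkm (0.83 ± 0.13). Of 16 unfolded protein response genes, 9 rose and 7 did not pass (11 rose adjusted over the list alone; mean 0.21, adjusted p = 0.000323; adjusted p = 0.376 with an estimated correlation), such as Manf (0.44 ± 0.07) and the transcription factor Atf4 (0.36 ± 0.05). Of 17 NRF2 targets, 6 rose, 1 fell and 10 did not pass (8 rose adjusted over the list alone; mean 0.17, adjusted p = 0.0244; adjusted p = 0.635 with an estimated correlation). Pgd of the pentose phosphate pathway rose (0.64 ± 0.07), and the glutathione transferase Gstm1 fell (-0.89 ± 0.19; -0.41 by another probe).

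The other 29 lists did not pass between the models. The cell cycle list had 1 member up and 27 not past (mean 0.05, adjusted p = 0.387), ciliated cells 11 not past (mean 0.02, adjusted p = 0.943), and endothelium 2 up and 16 not past, with a mean of -0.04 and a test pointing up (adjusted p = 0.94). Neutrophil markers had 6 up and 4 not past (mean 0.37, adjusted p = 0.0909). Up, down and not past were 4, 0 and 9 for type 2 cells (0.176), 4, 2 and 0 for type 1 (0.366), 2, 0 and 9 for club cells (0.192), and 1, 1 and 12 for fibroblasts (0.75). They were 2, 0 and 8 for smooth muscle (0.347), 2, 1 and 7 for cardiac muscle (0.29), 0, 0 and 7 for adipocytes (0.989), 0, 0 and 4 for mesothelium (0.784), and 1, 0 and 5 for red blood cells (0.601). Immune lists had 5, 1 and 7 for monocytes and macrophages (0.132), 1, 3 and 8 for T cells (0.396), 0, 1 and 8 for NK cells (0.359), 2, 0 and 7 for B cells (0.912), and 0, 2 and 5 for mast cells (0.225). Epithelial lists had 1, 0 and 8 for basal epithelium (0.546), 0, 0 and 9 for neuroendocrine cells (0.977; mean 0.02, median -0.02) and 2, 1 and 12 for gastrointestinal epithelium (0.366). They were 4, 2 and 6 for immediate early genes (0.372), 0, 1 and 15 for interferon response (0.964), 0, 2 and 8 for MHC class II (0.322), and 1, 1 and 20 for chemokines (0.864). The last were 4, 1 and 11 for proteases (0.132), 2, 1 and 8 for fatty acid synthesis (0.92), 4, 2 and 7 for p53 targets (0.182) and 1, 2 and 8 for embryonic genes (0.75). Adjusted over the list alone, the counts differed for type 2 cells (3 rose), endothelium and smooth muscle (1 rose each), embryonic genes (0 rose), and NK cells, interferon response, chemokines, proteases and circadian genes (0 fell each). Of the 8 driver and tumor suppressor genes, 2 rose, 2 fell and 4 did not pass. Of 12 circadian genes, 2 rose, 1 fell and 9 did not pass. Of 5 sex-linked genes, 3 fell and 2 did not pass; the same list had 1 fall and 4 not past for HER2 tumors against normal lung, and 3 rises, 1 fall and 1 not past for KRAS tumors.

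Session stands beside this comparison, since no session held tumors of both models and each model had only 2 sessions. The random block takes 1 correlation for all features and counts single extracts as units. Its p-values therefore do not fully measure the spread between sessions, and a call that stays is not thereby freed of session. With session as a random block (consensus correlation 0.1626), 69 features were called, 50 higher and 19 lower, all among the 88, and 55 of 117 named genes stayed past the adjusted p. Procr (adjusted p = 2.27e-05), Cd177 (3.07e-06), Epgn (0.000185), Sbk1 (9.22e-06), Ereg (0.00412) and Kras (3.75e-22) stayed past it. Gkn2 (1.76 ± 0.67, 0.0714), Chia1 (-1.34 ± 0.61, 0.145), Lrrn3 (-1.31 ± 0.48, 0.0635), Krt79 (1.06 ± 0.44, 0.102) and Gstm1 (-0.88 ± 0.32, 0.0544) did not, with changes of the same size and larger SEs. The 7 lists held, with means of 0.55, 0.39, 0.24, 0.25, 0.43, 0.21 and 0.16 in the order given above. With session as a fixed block linked through 3 normal lungs, 42 features were called, 7 higher and 35 lower, and only 5 were among the 88. Across features the changes did not keep their size there. They correlated with those of the fit without a block at 0.5494, and 320 features reached 2-fold against 90. In that fit Kras was -4.72 (adjusted p = 3.01e-11), Eif2s3y 0.17 and Ddx3y 0.28. Changes of similar size with larger SEs did not pass there for Procr (2.01 ± 0.75, adjusted p = 0.435), Cd177 (1.85 ± 0.59, 0.29), Epgn (1.95 ± 0.71, 0.403), Sbk1 (-2.82 ± 0.85, 0.232) and Ereg (1.25 ± 0.69, 0.777). Sessions differed within the models too: HER2 tumors of session 2 and session 1 differed in 61 features (12 higher, 49 lower), 2 of them among the 88, and 11812 passed the adjusted p alone, while KRAS tumors of session 4 and session 3 differed in 4 features and 679 passed.

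**Figure D3:**
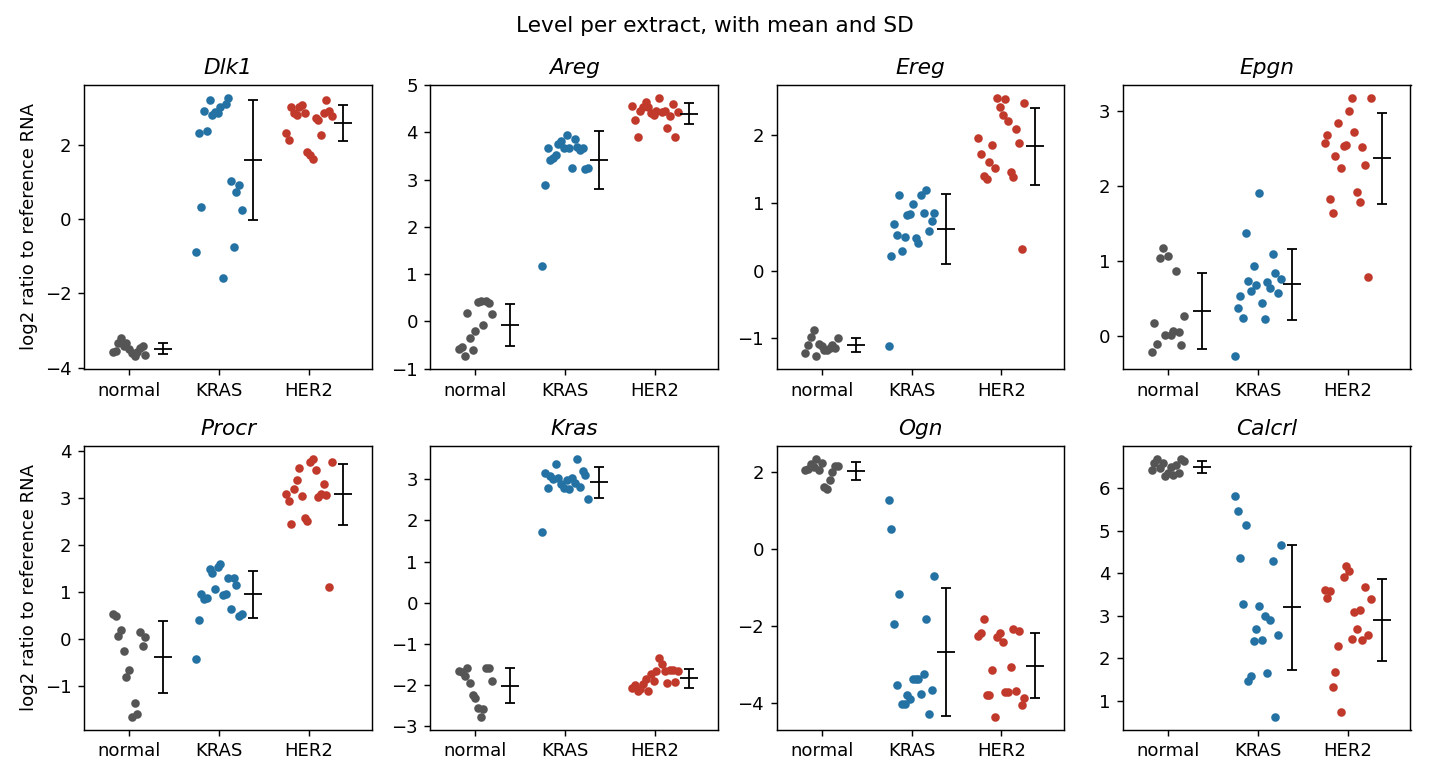
Log2 ratio to reference RNA of 8 genes in each of 13 normal lungs, 18 KRAS tumors and 18 HER2 tumors, 1 point per extract, with the mean and SD of the group as bars. Areg, Ereg and Procr lie highest in HER2 tumors, Kras in KRAS tumors (1.71 or more), and KRAS tumor 1 lies nearest the normal lungs in Areg (1.18), Ogn (1.29) and Calcrl (5.82).

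List scores were correlated across the 18 tumors of each model, in 6 relations, to ask whether alveolar type 2 markers or ERK output vary with proliferation. None passed by permutation test (two-sided, 100000 resamples). In HER2 tumors, type 2 markers and the cell cycle gave r = 0.02 (p = 0.939, rho = 0.04), with -0.7 in session 1 and 0.36 in session 2. ERK output and the cell cycle gave r = -0.08 (p = 0.753, rho = -0.31), with 0.39 and -0.87, and type 2 and gastrointestinal markers r = 0.08 (p = 0.782, rho = -0.04), with -0.14 and 0.26. In KRAS tumors the same relations gave r = 0.24 (p = 0.338, rho = 0.02), 0.45 (p = 0.0581, rho = 0.37) and -0.29 (p = 0.245, rho = -0.27). Within sessions 3 and 4 these were 0.34 and 0.16, 0.5 and 0.53, and 0.07 and -0.66. Without the 2 tumors farthest from the median, r was -0.02, -0.17 and -0.04 in HER2 tumors and -0.36, 0.26 and -0.53 in KRAS tumors. The smallest adjusted p was 0.349 for r and 0.574 for rho, and the largest difference between models, -0.53 for ERK output, had adjusted p = 0.488.

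The lungs of the strains were compared because normal lung of either could serve as a baseline. The 129SvEv lungs had more Gdpd3, a lysophospholipase (3.15 ± 0.12, adjusted p = 3.8e-07), and more of the interferon-induced Gbp2b (2.91 ± 0.6) and Ifi202b (2.3 ± 0.14, adjusted p = 1.22e-05), besides Erdr1 (2.41 ± 0.29) and Rbm45 (2.32 ± 0.53). They had less of the small GTPase Rab7b (-2.98 ± 0.28, adjusted p = 0.000248), Rpgrip1 (-2.75 ± 0.44), the annexin Anxa8 (-2.46 ± 0.6), Prdm16 (-2.44 ± 0.41) and Rrp7a (-2.32 ± 0.5). Each held in 3 of 3 lungs. In all, 306 of 32391 features were called, 111 higher and 195 lower in 129SvEv. Of these, 163 had a symbol (62 higher, 101 lower), and 2225 passed the adjusted p alone. Other probes of Rpgrip1 ran from -2.97 to 0.02, and another probe of Rrp7a gave 0.02. All 6 lungs were in session 5.

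The uninduced chimera lungs were compared with the mean of C57Bl6 and 129SvEv lungs to see where they differ. They had more of the kallikrein Klk1b24 (1.41 ± 0.25, adjusted p = 0.017), the cold-induced RNA-binding protein Cirbp (1.24 ± 0.22), Ifi202b (1.21 ± 0.11), Gdpd3 (1.15 ± 0.1, adjusted p = 0.000447) and Vmn1r237 (1.15 ± 0.26). They had less of the lipid kinase Pi4k2b (-1.22 ± 0.08, adjusted p = 0.000134), the secretory protein Agr2 (-1.08 ± 0.23), the retinoid carrier Rbp7 (-1.07 ± 0.25), the heat shock protein Hsph1 (-1.03 ± 0.22) and the imprinted Mest (-1.01 ± 0.16). All 4 lungs lay beyond the mean of the strains for each gene, but that mean lies between strains that differ. Beyond all 6 strain lungs lay 4 of 4 chimera lungs for Cirbp, Agr2 and Rbp7, 3 for Klk1b24, Vmn1r237, Pi4k2b and Mest, 2 for Hsph1, 1 for Ifi202b and 0 for Gdpd3. Ifi202b and Gdpd3 were also among the strain differences. Pi4k2b and Klk1b24 varied widely over the 6 strain lungs too. Pi4k2b ran from -0.59 to 1.71 there, against -0.77 to -0.59 in the chimera lungs, and Klk1b24 from -0.11 to 2.44, against 1.91 to 2.76. In all, 14 of 32391 features were called, 9 higher and 5 lower, 13 of them with a symbol, and 1173 passed the adjusted p alone. The count rested on single lungs, being 6 without chimera lung 2, 59 without chimera lung 3 and 9 without C57Bl6 lung 1.

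**Figure D4:**
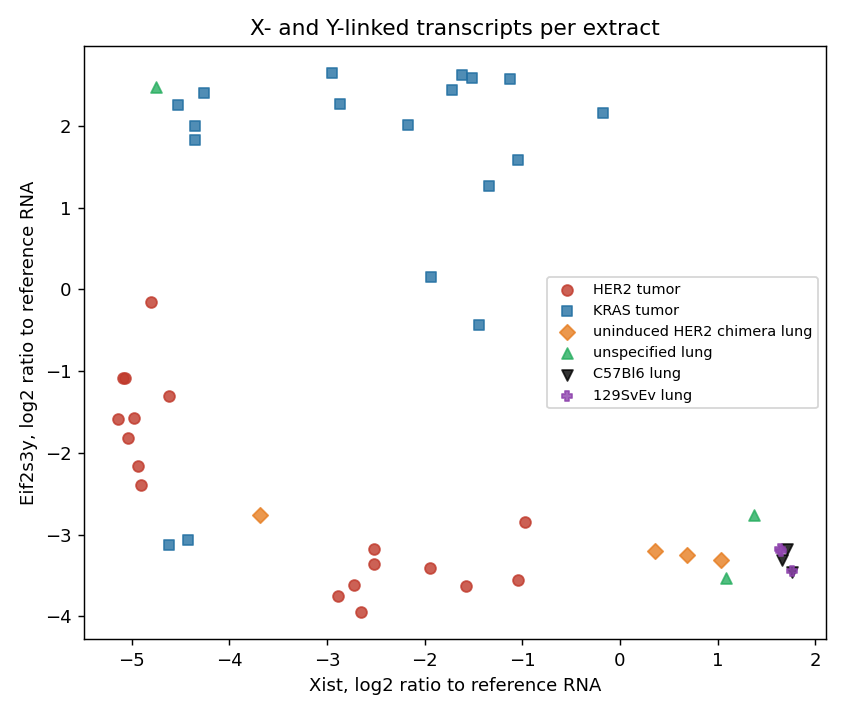
Log2 ratio to reference RNA of Xist (x axis) and of the Y-linked Eif2s3y (y axis), 1 point per extract, coloured by group. C57Bl6 and 129SvEv lungs lie together at high Xist (1.64 to 1.76), HER2 tumors at or below -0.97 in Xist, and most KRAS tumors at high Eif2s3y (median 2.08).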

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

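The tests of the strain index and of session (for Xist and for the heart, fat and mesothelial lists) and the fits that leave out KRAS tumor 1, or KRAS tumors 1 and 2, were chosen after the results were seen; the other tests here were chosen before. Single samples stood apart in 6 of 51 levels and list scores tested in the 4 uninduced chimera lungs, where Dixon's ratio exceeded its 95% critical value, which marks a sample far from the others. Chance gives about 1 in 20, or 2.55 of 51. The Xist level of lung 1 was -3.68, against 0.36 to 1.04 in the others (ratio 0.8558), and Rbp7 of lung 3 was 0.6, against 1.22 to 1.34 (0.846). The score of type 1 cell markers was 3.23 in lung 2, against 3.12 in the nearest lung (0.9782), and that of ciliated markers 2.28 in lung 1, against 2.44 to 2.47 (0.8331). The mesothelial score was -0.78 in lung 4, against 0 to 0.03 (0.9724), and that of basal and squamous markers 0.85 in lung 1, against -0.02 to 0.1 (0.8589).

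Xist was lower in the tumors of both models than in normal lung, and as groups only KRAS tumors had higher Y-linked transcripts. HER2 tumors were mixed. In HER2 tumors 1 to 7, 13 and 14, Xist was -5.14 to -4.62 and Eif2s3y -2.39 to -0.15. These Eif2s3y levels lay above all normal lungs (-3.53 to -2.76) except unspecified lung 2 (2.48). Tumors may have grown from 129-type cells of the chimeras rather than from host cells. Over 117 genes that differed between the strains by at least 1.5 on the log2 scale, an index of 0 for C57Bl6 and 1 for 129SvEv had a median of 0.84 in the 36 tumors (0.79 over genes higher in 129SvEv, 0.85 over those lower) against 0.46 in the chimera lungs, higher by 0.3 in HER2 tumors (exact permutation p = 0.00232, adjusted 0.00465, 18 of 18 above the chimera median) and by 0.26 in KRAS tumors (exact permutation p = 0.00875, adjusted 0.00875, 18 of 18), as that origin needs, but chimera lung 1 (0.94) and the unspecified normal lungs (0.68, 0.68 and 0.97) were high too, so the index does not single it out. Session stays open for the difference from normal lung, because the blocked values rest on few lungs: Xist was -3.62 (SE 1.63) in HER2 tumors with 1 normal lung, and in KRAS tumors Xist went from -3.06 to -0.76 (SE 1.35), Eif2s3y from 4.12 to 0.58 (SE 1.15) and Ddx3y from 2.15 to 0.14 (SE 0.62) with 2 lungs at opposite ends (Xist -4.75 and 1.37, Eif2s3y 2.48 and -2.76), a spread within 1 session that a shift common to the session does not give. The sex of the animals and of the cells that formed the chimeras, which the labels do not give, remains an untested biological explanation.

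Changes against normal lung were smaller in KRAS than in HER2 tumors, with an SD over features 0.8568 times as large (bootstrap SE 0.06112). Normal lung tissue in KRAS extracts could shrink falls more than rises. Over 585 genes higher and 1254 lower in both models, the gap between the models was 0.24 for the rises and 0.16 for the falls, a difference of -0.07 (bootstrap SE 0.06), which does not decide. Arrays of unequal spread stay open, since the ratio was 0.8676 (SE 0.06784) with arrays scaled to equal spread, and so does KRAS tumor 1, since the ratio was 0.8985 (SE 0.04882) without it and 0.9282 (SE 0.0473) without KRAS tumors 1 and 2. A difference between the drivers, which the design names, remains untested beside these.

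Cardiac muscle and fat lists fell in both models and the mesothelial list in KRAS tumors, while in HER2 tumors the latter did not pass (adjusted p = 0.0668); none of them passed with an estimated correlation (adjusted p = 0.497 with an estimated correlation for each list that had passed). Neighbouring tissue carried into some normal lung extracts may contribute: all 3 list scores varied more over the 13 normal lungs (SD 0.23, 0.64 and 0.28) than the median of the 21 cell type lists (0.15), in a test that could have come out otherwise. Carry-over into only some lungs would not put tumors below every normal lung. Below all of them lay 18 HER2 and 17 KRAS tumors of 18 for cardiac muscle, 17 and 17 for adipocytes, and 17 and 15 for mesothelium. This argues against carry-over into some lungs as the whole cause. Session as the whole cause is argued against only by the 2 normal lungs that shared session 4 with KRAS tumors. With session as a block, the weakest change in KRAS tumors was -1.62 (SE 0.46), with -2.73 (SE 0.44) for cardiac muscle and -1.88 (SE 0.47) for adipocytes. One of these lungs, unspecified lung 2, had the highest cardiac score of the 13 normal lungs (3.293). Carry-over could thus add to the blocked change of cardiac muscle, and the block does not part it from carry-over. Normal lung itself holds cardiac muscle in its veins, so a lower share of normal lung in the tumors remains untested as a biological explanation.

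Other splits of the same extracts into groups of the same sizes were drawn. As many calls as the real split came from 1 of 100 splits (the real one) for HER2 tumors against normal lung (2710, highest other 0). The same held for KRAS tumors against normal lung (2033, highest other 751), HER2 against KRAS tumors (88, 63) and the overlap (1839, 0). No smaller share was possible with these splits. Splits that mix tumors with normal lungs widen the spread within groups, which lowers their counts. The splits also exchanged single extracts, which may share animals, and did not keep sessions whole. HER2 tumors of sessions 2 and 1 alone differed in 61 features. Random exchange of extracts thus seldom gave as many calls, but these splits cannot tell the groups from sessions or animals. For 129SvEv against C57Bl6 lung the 10 splits are too few for a share under 0.05 (1 of 10; 306, highest other 0). For the chimera lungs, 11 of 100 splits gave as many calls as the real 14 (highest other 21), and for the gene list tests 20 of 100 gave as many passing tests as the real 39 (highest other 53), so chance cannot be excluded for either.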

How the results depend on the processing

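The session block linked through unspecified normal lungs, the session block of the gene list tests and the fits that leave out KRAS tumors 1 and 2, HER2 tumor 9 or chimera lung 1 were chosen after seeing the data. Counts of called features were within 1.5 times the reported count in 18 of 21 alternatives for HER2 tumors against normal lung (2558 to 3943), 19 of 22 for KRAS tumors (1907 to 2334), 13 of 18 between the models (69 to 94), 10 of 13 between the strains (261 to 331) and 7 of 12 for the chimera lungs (10 to 21). Nearly all features with a 2-fold change also passed the adjusted p (2710 of 2715, 2033 of 2036 and 88 of 90 in the tumor comparisons), so the fold requirement sets these counts, and equal counts under other weights or filters say little of stability. Signal over background limits the dim features: without the filter, the counts of called features in the tumor comparisons stayed at 2710, 2033 and 88.

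With the scanner software's log ratios the counts were 4614, 3643, 173, 690 and 57 in that order and 3276 for the overlap, and with the deposited values 4618, 3649, 174, 685 and 56; of the reported calls, 2608, 1957, 79, 290 and 13 were among those from the log ratios. The cause was not tested. Between the models the share of higher calls went from 72.7% to 56.1% (97 and 76), to 55.7% with the deposited values (97 and 77) and to 61.2% with median centring (49 and 31). Without the fold requirement, by construction, the counts were 22701 (51.8% higher), 19434 (53.5%), 12033 (47.4%), 2225, 1173 and 16968 for the overlap. Between the models, a test against a 1.5-fold change left 35 features and the linked session block 42 (16.7% higher; the cause was not tested). For the chimera lungs, median centring gave 6, Cy3 arrays alone 26 (20 and 6) and 1 fit of all extracts 21 (19 and 2); the cause was not tested. Leaving out 1 lung at a time gave 221 (without C57Bl6 lung 2) to 283 (without 129SvEv lung 3) for the strains and 6 (without chimera lung 2) to 59 (without chimera lung 3) for the chimera lungs, where 9 remained without C57Bl6 lung 1. With an estimated correlation, 0 of the gene list tests passed, against 40 with the log ratios, 44 without the filter, 37 with chimera lungs as the only normal lungs, 39 without KRAS tumor 1 and 42 with the session block.

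Without KRAS tumor 1, the counts were 2219 for KRAS tumors, 80 between the models and 1966 for the overlap; without KRAS tumors 1 and 2 they were 2334 and 86, without HER2 tumor 9 2726 and 90, and without chimera lung 1 2706 and 2041. The replicate block between the strains gave 324 calls (114 and 210); same-numbered lungs correlated at -0.07, -0.19 and -0.04, so the numbers do not pair the lungs. No correlation passed under any alternative, and 3 turned sign: type 2 markers with the cell cycle in HER2 tumors (-0.02 with the log ratios) and in KRAS tumors (-0.06 without KRAS tumor 1), and type 2 with gastrointestinal markers in HER2 tumors (-0.16 at unit variance). Of single genes, Trp53 in HER2 tumors turned to -0.11 with median centring, -0.05 with scaling and -0.02 with Cy5 alone, and Cdkn2a between the models to 0.22 with the log ratios; the cause was not tested. Of 470 named gene results past the adjusted p, 437 held with the log ratios, 442 with median centring, 445 with scaling, 465 without the filter, 431 with Cy3 and 427 with Cy5. Session cannot differ between the strains, all in 1 session, and a session block over the 13 normal lungs gave 312 calls.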

Other observations

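No test in this part was chosen after seeing the results, but the strain index named in its last paragraph was devised after they were seen. Chemokine, protease and stress genes of lists that did not pass as a whole changed singly in both models. Cxcl1, which attracts neutrophils, rose by 2.17 ± 0.19 in HER2 tumors and 2.14 ± 0.22 in KRAS tumors, and Cxcl12, a chemokine of stromal cells, fell by 2.27 ± 0.27 and 2.23 ± 0.36. The macrophage elastase Mmp12 rose by 2.09 ± 0.2 and 1.98 ± 0.19. Cdkn1a, the cell cycle inhibitor p21, rose by 1.6 ± 0.12 and 0.92 ± 0.14, and differed between the models by 0.68 ± 0.11. Akr1b8, an aldo-keto reductase, rose by 1.85 ± 0.05 and 1.49 ± 0.12, and Id2, an inhibitor of differentiation factors, by 1.8 ± 0.17 and 1.8 ± 0.24. All of these had 18 extracts in each model and 13 normal lungs.

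The 3 normal lungs of unspecified strain gave Xist levels of 1.09, -4.75 and 1.37, Eif2s3y levels of -3.53, 2.48 and -2.76, and strain index values of 0.68, 0.68 and 0.97 in the order of their numbers. The 4 chimera lungs had index values of 0.94, 0.53, 0.33 and 0.39.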
